A study of Mus musculus with 19 samples.

How the data were processed

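Polyadenylated RNA from the kidneys of 19 mice was sequenced, 1 library per mouse, in 4 groups defined by strain and treatment per the labels. All libraries carry batch label 2. The library numbers in the labels run in blocks by group, and what their order reflects is not given. An effect of that order could not be told apart from strain or treatment. The deposited table holds estimated counts (expected counts) per gene, which the values show: between 4.63% and 10.1% of the values in a library were not whole numbers, and totals differed between libraries. Reads were trimmed with Trim Galore 0.6.7 and aligned with STAR 2.7.9a to mm39 (GRCm39), per the submitters' processing notes. The tool that produced the estimated counts and its annotation are not given in the sources used here. Counts were rounded to whole numbers before testing. The table holds 40413 genes, named by symbol, of which 29589 had a count in any library.

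Total counts per library ran from 21400111 to 40998650. Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F-test, robust fit) under R 4.3.3, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. All groups entered 1 fit, with no covariate. The comparisons were the strain difference in each arm, the Cmpd17b effect in each strain and their interaction. The design, the 44 gene lists, the 26 single genes, the rule for naming genes and the alternative settings were fixed before the data were examined. A list needed 5 tested members, which 42 had. Lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry).

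The fit without the library labelled BPH/2J Cmpd17b replicate 1 was chosen after its profile had been seen, as was the list of 30 heart muscle genes. Every alternative setting was repeated in that fit. Without the library the biological coefficient of variation was 0.251, against 0.418 with it. Genes called enriched in that library were at 20 CPM or more in it and at 20 times or more the level of every library of the 3 other groups. Group values in CPM are on the TMM scale of the 18 libraries.

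Genes were named by a rule: per comparison, among called genes with a mean log2 CPM of at least 1 and a symbol that is not a predicted locus, the 6 largest rises, the 6 largest falls and the 6 smallest p-values not yet named, up to 4 members of each called list, and the 26 single genes. Where fewer than 6 passed, the 5 with the smallest p were given. Heart muscle genes below that level, Fgf18, Sprr2a1 and Sagsin1, which only DESeq2 called, and Noxred1, Rsc1a1 and Sap18b were named after their values had been seen. 1 gene that the rule names is not reported here.

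Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter, a filter of 1 CPM in 4 libraries, only the compared groups, a fit that is not robust, 1 surrogate variable (sva 3.50.0), the animal number as a covariate, a log2 fold change of at least 1, and leaving out each library in turn. A covariate for sex was not run, since every library had the Y-linked gene Ddx3y at 39.4 CPM or more and Xist at 0.675 CPM or less. Other splits of the same mice were drawn 100 at a time. An earlier and smaller draw had been made for speed, and the number was set back to 100 because a result at the border of the threshold had changed sides with the draw.

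The reversal measure was compared with 100 simulated sets of unchanged groups, which held no strain difference, and repeated over 20 divisions of the vehicle BPH/2J mice. Tests were checked on simulated data with 200 changed genes, and false calls made up 2.88% to 6.92% of calls. The changed genes were drawn from those above a floor of mean CPM, and genes varied independently within groups. Exact permutation tests were two-sided. Transcript lengths and the order of genes along chromosomes came from annotation of an earlier build and were used for lengths and neighbours only. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.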

Results

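Kidney RNA was sequenced from 19 mice of the BPN/3J and BPH/2J strains. BPN/3J mice have normal blood pressure and BPH/2J mice are hypertensive. The mice received vehicle or Cmpd17b, a compound that acts on formylpeptide receptors, at 50 mg/kg/day for 28 days. The groups held 4 vehicle BPN/3J mice, 5 treated BPN/3J mice, 5 vehicle BPH/2J mice and 5 treated BPH/2J mice. Total counts per library ran from 28527513 to 40998650 in vehicle BPN/3J mice and from 25546681 to 34244282 in treated BPN/3J mice. They ran from 25840891 to 33616451 in vehicle BPH/2J mice and from 21400111 to 30950623 in treated BPH/2J mice. Values per gene are in CPM, the counts of a gene relative to its library's total after TMM scaling, given as mean ± SD. No genome coordinates are given, since an annotation of the build used by the submitters was not used here.

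The library labelled BPH/2J Cmpd17b replicate 1 held heart muscle transcripts in place of kidney transcripts. Its Myh6 level was 14200 CPM before TMM scaling, against at most 28.3 CPM in any other library, and its Mb level was 13355 CPM against at most 22.9 CPM. Slc34a1, a proximal tubule transporter, was at 5.945 CPM in it. The median proximal tubule gene stood at 0.227% of its level in the other 18 libraries, the median thick ascending limb gene at 0.237%, the median collecting duct gene at 0.411% and the median podocyte gene at 49.3%. Its highest correlation with any other library was 0.713, whereas the lowest correlation between any 2 of the other 18 was 0.897. The planned comparisons used all 19 libraries. A second set of comparisons without this library was added after its profile had been seen, and both are given below.

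**Figure D1:**
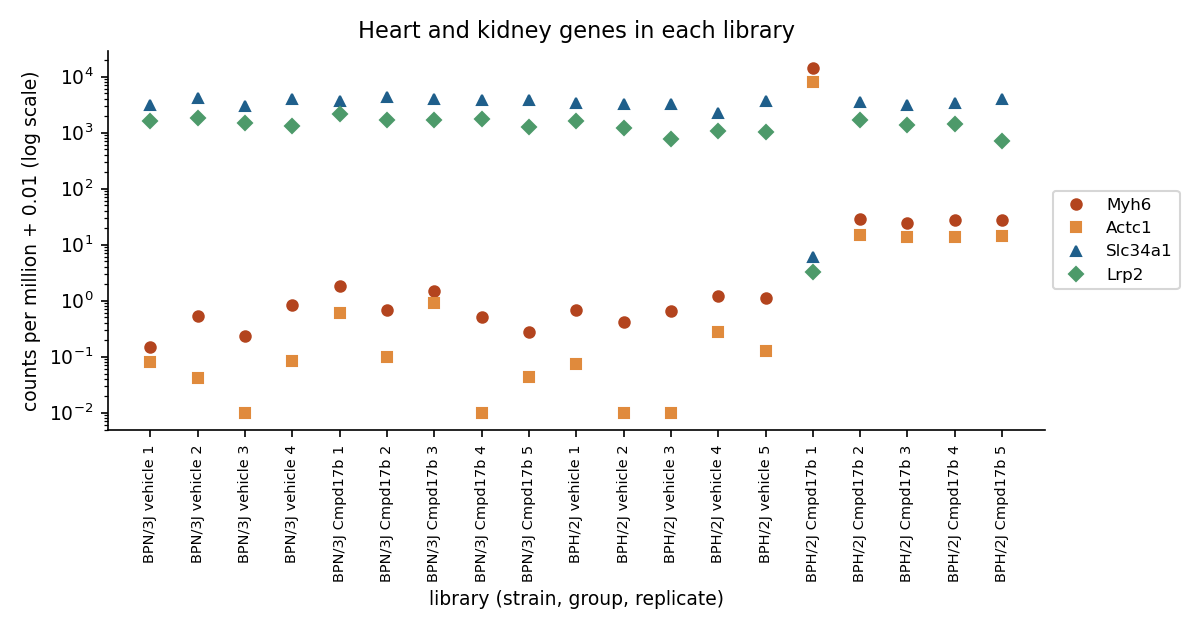
CPM of Myh6 and Actc1 (heart) and of Slc34a1 and Lrp2 (kidney) in each of the 19 libraries, on a log axis with 0.01 added; 1 point is 1 library. BPH/2J Cmpd17b replicate 1 has Myh6 at 14200 CPM and Slc34a1 at 5.945 CPM.

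The 18 other libraries separated by strain on the first principal component, which held 58.9% of the variance among the 500 most variable genes. The second component held 11.9%. Treated and vehicle mice of a strain overlapped on both components.

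**Figure D2:**
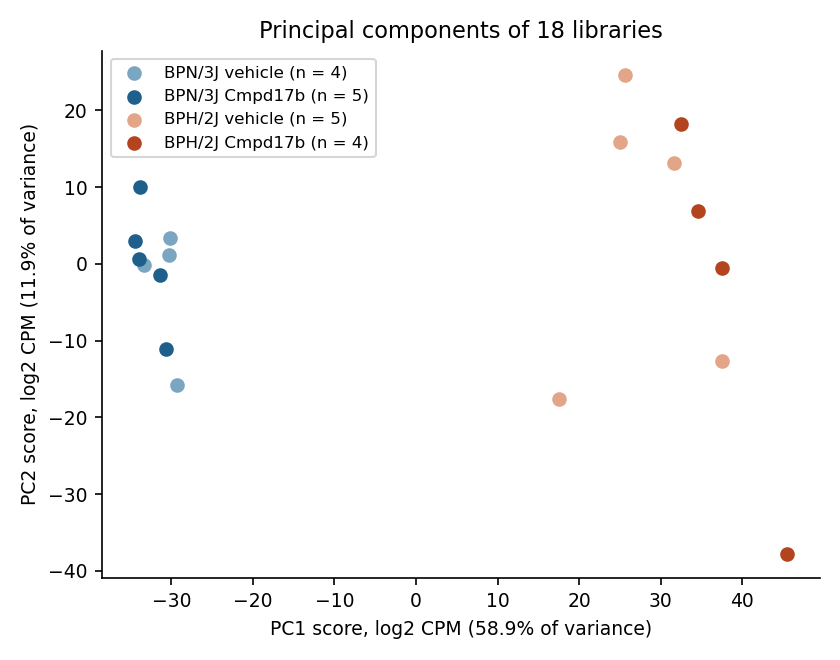
Scores of 18 libraries on the first and second principal components of log2 CPM, coloured by group; 1 point is 1 mouse. The first component, with 58.9% of the variance, separates BPH/2J from BPN/3J mice.

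The comparison of the strains under vehicle asks how the BPH/2J kidney differs from the BPN/3J one. Genetic background and hypertension go together in it and cannot be told apart. Hdc, which encodes histidine decarboxylase, was at 421 ± 117 CPM in BPH/2J (n = 5) and 2.08 ± 1.56 CPM in BPN/3J (n = 4). Ttr was at 185 ± 52.7 CPM against 1.91 ± 0.662 CPM, Plppr1 at 24.7 ± 5.99 CPM against 1.78 ± 0.176 CPM, and Gas6 at 174 ± 39.2 CPM against 27.7 ± 4.54 CPM. Lower in BPH/2J were Atg4a, at 4.9 ± 2.61 CPM against 37.5 ± 1.81 CPM, Mcm6, at 2.5 ± 2.29 CPM against 24.8 ± 4.92 CPM, and Dnajc28, at 3.08 ± 0.589 CPM against 14.1 ± 1.44 CPM. The ranges of the groups did not overlap for any of these genes. With all 19 libraries, edgeR called 566 genes of 16522 at an adjusted p under 0.05, 317 higher and 249 lower in BPH/2J. With 18 libraries it called 1766 of 16421, 955 higher and 811 lower. All 563 of the 19-library calls that were tested in both fits were called in the same direction with 18 libraries. Both fits use the same vehicle libraries for this contrast, so the shared direction is not independent support.

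In the 18-library fit of edgeR, the log2 fold change was 7.65 for Hdc (SE 0.482, adjusted p 5.92e-09) and 6.59 for Ttr (SE 0.33, adjusted p 3.23e-10). It was 3.79 for Plppr1 (SE 0.202, adjusted p 5.69e-10) and 2.84 for Cyp4b1 (SE 0.186, adjusted p 8.55e-09). Angptl7 also rose. Among genes with a mean log2 CPM of at least 1, the largest fall was Ugt1a10 at -4.93 (SE 0.821, adjusted p 0.000565). Tagap at -3.66 (SE 0.443, adjusted p 1.9e-05), Mcm6 at -3.34 (SE 0.408, adjusted p 2.09e-05), Atg4a at -2.95 (SE 0.246, adjusted p 2.16e-07), Tmem267 and Akr1c18 also fell. In the 19-library fit Gas6 and Zfp605 were higher and Dnajc28 and Nxpe3 lower. Serpina1a, Serpina1d, Eno1b, Eif3j2, Rnaset2b, Ugt1a10, Ahcyl, Il11ra2 and Zfp969 also met the naming rule in at least 1 fit, but each has close relatives whose reads the counting could have split, so their values are uncertain. With 18 libraries Ahcyl rose by 5.52 on the log2 scale (edgeR adjusted p 3.13e-10) while its relative Ahcy, chosen after its values had been seen, fell by 2.12 (edgeR adjusted p 1.95e-06).

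Among the 26 genes chosen before the data were examined, 23 were tested. Fpr1 and Fpr2, which encode formylpeptide receptors, were among those not tested with all 19 libraries. With 18 libraries, edgeR called Ccn2, Col3a1, Fn1, Acta2, Icam1 and Nos3 higher and Ren1 lower in vehicle BPH/2J mice, and 12 were higher and 2 lower when adjusted over the list alone. Nos3 was at 5.81 ± 0.753 CPM in BPH/2J (n = 5) and 2.98 ± 0.505 CPM in BPN/3J (n = 4), with an edgeR log2 fold change of 0.96 (adjusted p 0.00362). Ren1 was at 75.9 ± 27.4 CPM against 150 ± 16.8 CPM, with an edgeR log2 fold change of -0.98 (adjusted p 0.0346). Col3a1 was at 18.1 ± 16.1 CPM against 6.24 ± 1.37 CPM, its group ranges overlapped, and BPH/2J vehicle replicate 2 was at 46.4 CPM where the 4 others of its group had a mean of 11 CPM. Without that library its log2 fold change went from 1.54 to 0.82 (edgeR adjusted p 0.0674). Of these 7 calls only Nos3 remained in all 18 refits that left out 1 more library, and each of the others was lost in 3 to 6 of them. Over all comparisons there were 8 such calls, which became 2 without BPN/3J vehicle replicate 1 or 3, 4 without BPN/3J vehicle replicate 2 or BPH/2J vehicle replicate 2, and 13 without BPH/2J vehicle replicate 1. With all 19 libraries, edgeR called 0 of the 23; 3 were higher when adjusted over the list alone (Ccn2, Fn1 and Icam1).

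**Figure D3:**
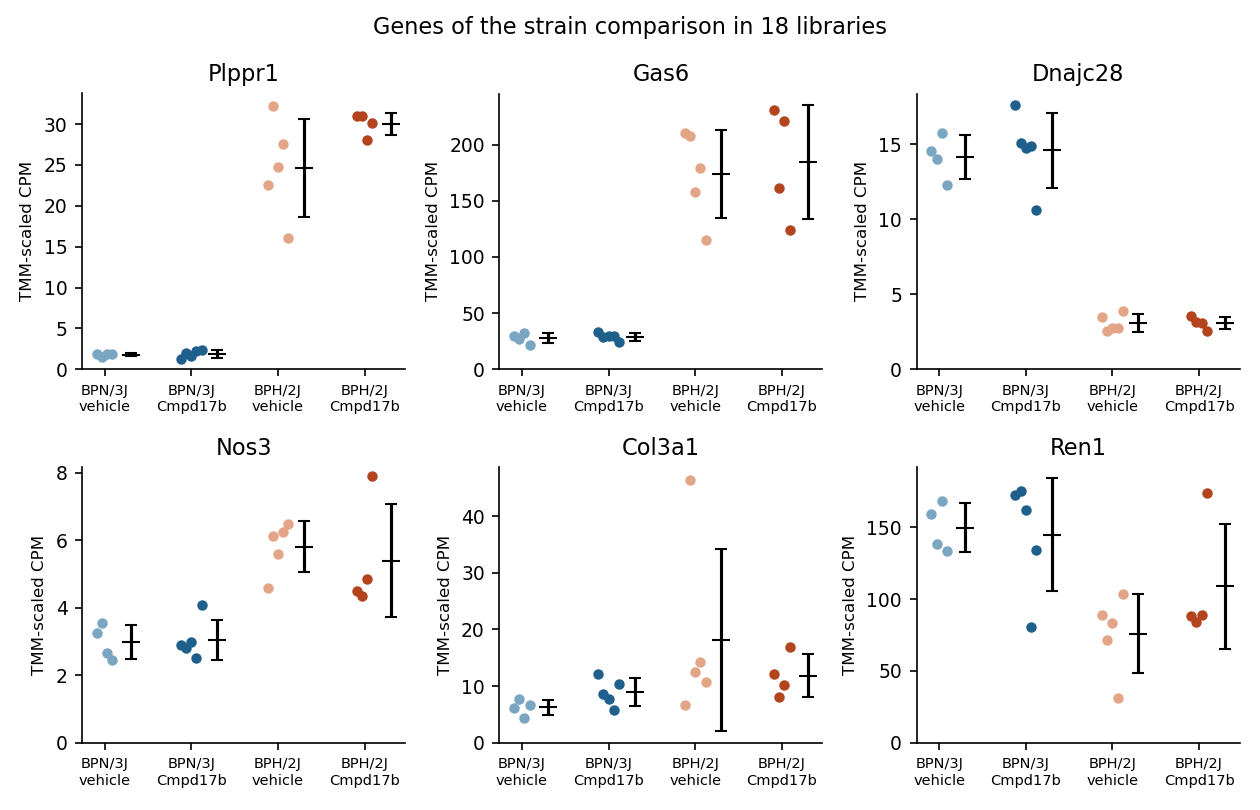
TMM-scaled CPM of 6 genes in 18 libraries; coloured points are mice, and the black mark with bars is the mean ± SD of the group. Plppr1 lies at 24.7 ± 5.99 CPM in vehicle BPH/2J mice and at 1.78 ± 0.176 CPM in vehicle BPN/3J mice.

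Matrix, podocyte, liver and tubular injury lists were higher in vehicle BPH/2J than in vehicle BPN/3J mice, and distal convoluted tubule and proximal tubule lists were lower, by limma's camera with a preset correlation in the 18-library fit, but with an estimated correlation camera called 0 lists in either fit. The mitochondrial share of counts was also higher, at 15.8% to 21.2% in vehicle BPH/2J against 13% to 16% in vehicle BPN/3J libraries, as was the share of the 10 most abundant genes, at 20.1% to 28.7% against 17.5% to 21.6%. The liver list had 4 of 11 tested genes higher, and 4 when adjusted over the list alone. Ttr and Serpina1a were among them, and the value of Serpina1a is uncertain because of its close relatives. In that fit the matrix list had 12 of 31 tested genes higher and 0 lower, with 20 higher when adjusted over the list alone, led by Tnc, Sparc, Dcn and Col5a2. BPH/2J vehicle replicate 2 stood out as high in the matrix genes Col1a1 and Col3a1. Without that library, lists called over all comparisons numbered 73, the fewest of the 18 refits. The podocyte list had 6 of 16 higher, with 9 adjusted over the list alone, among them Cdkn1c. The injury list had 4 of 23 higher, with 6 adjusted over the list alone, led by Cp and Clu. Of 42 lists tested, that test called 15 with 18 libraries and 11 with 19. The estimated-correlation adjusted p with 18 libraries was 0.564 for the matrix list and 0.53 for the podocyte and injury lists. Fry, which tests whether a list's genes move on balance in 1 direction, called 14 lists with 18 libraries and 3 with 19.

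The comparison of the strains under Cmpd17b repeats the strain contrast in mice that share no library with the vehicle contrast. Hdc, Ttr, Plppr1, Angptl7 and Cyp4b1 were again higher in BPH/2J, and Tagap, Akr1c18, Tmem267 and Atg4a lower. Hdc was at 454 ± 49.7 CPM (n = 4) against 0.957 ± 0.332 CPM (n = 5), and Plppr1 at 30 ± 1.37 CPM against 1.87 ± 0.441 CPM. H2-Ab1, an MHC class II gene, was lower in BPH/2J, at 19.6 ± 6.54 CPM against 73 ± 33.9 CPM (edgeR log2 fold change -1.9, SE 0.376, adjusted p 0.00216). With 18 libraries edgeR called 1701 genes, 937 higher and 764 lower. The 4 treated BPH/2J libraries of that fit also held heart transcripts, which may have added to these calls. Without the genes enriched in the library with the heart profile, edgeR called 1607, 875 higher and 732 lower. With all 19 libraries it called 1446, 980 higher and 466 lower, and there the largest rises among genes with a mean log2 CPM of at least 1 were Myh6, Pln, Ttn and Tnnc1, which the library with the heart profile carries, and Serpinb8 and Cfd were among the falls. The fall of Cfd rested on BPN/3J Cmpd17b replicate 1, at 50.6 CPM where the 4 others of its group had a mean of 2.78 CPM, and without it the log2 fold change went from -4.33 to -2.18 (edgeR adjusted p 0.246). Thrsp was lower with 18 libraries (edgeR log2 fold change -3.64, adjusted p 0.0494), and without the same library this became -1.68 (edgeR adjusted p 0.249). That library was also the highest of its group in the fat cell genes Adipoq (13.6 CPM), Cidec (15.6 CPM) and Adrb3 (7.1 CPM), which were chosen after their values had been seen. Of the 18-library calls, 1109 were called in both arms, all in the same direction, with 578 higher and 531 lower where independent lists would share 54.5 and 37.7. The arms share 1 fit and its estimate of each gene's spread. Their calls are therefore not independent, and these chance counts may be too low. The correlation of log2 fold changes between the arms was 0.765 across 16421 genes, which are not independent replicates.

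In treated mice the MHC class II list had 7 of 10 tested genes lower, with 8 lower when adjusted over the list alone, led by H2-Ab1, H2-DMa and Ciita, but camera with an estimated correlation did not call it (adjusted p 0.779 with 18 libraries). The red blood cell list had 3 of 6 higher, with 6 adjusted over the list alone, led by Slc4a1 and Hbb-bs. Camera with the preset correlation called 6 lists with 18 libraries and 13 with 19, fry called 8 and 5, and camera with an estimated correlation 0 in either fit (adjusted p 0.779 for the red blood cell list with 18 libraries). The liver list was called higher although its median log2 fold change was -0.11, since Ttr and Serpina1a carried its mean of 0.74. Of the 23 tested genes chosen beforehand, edgeR called Nos3 alone, in both fits, and adjusted over the list alone there were 1 with 18 libraries and 4 with 19. A difference called in only 1 arm was not shown to differ between the arms, which the interaction below tests.

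**Figure D4:**
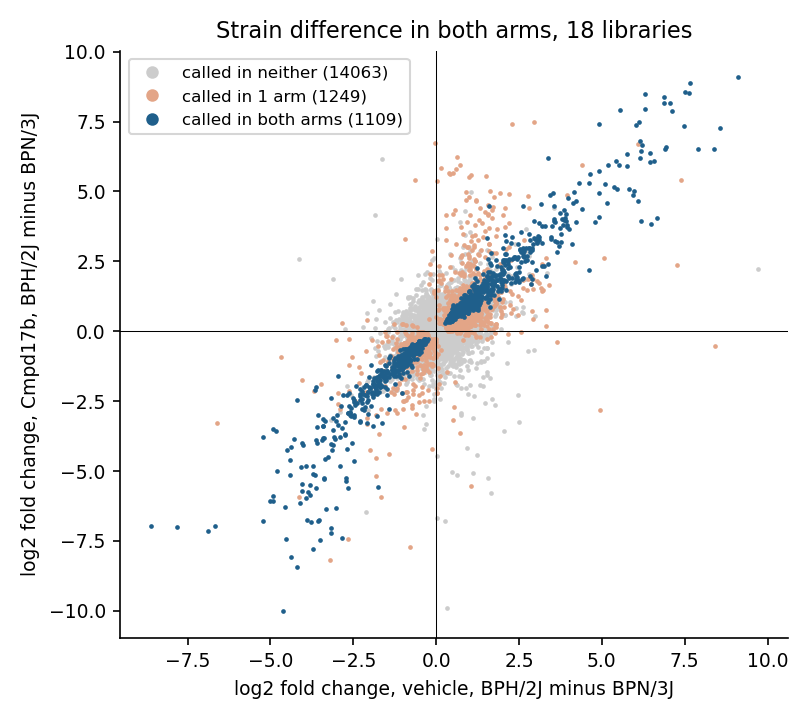
Log2 fold change of BPH/2J over BPN/3J under Cmpd17b (vertical) against vehicle (horizontal) for 16421 genes in 18 libraries; 1 point is 1 gene. The 1109 genes called in both arms lie on the same side of 0 in both.

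The effect of Cmpd17b in BPH/2J asks whether the compound changes the hypertensive kidney. The genes that edgeR called were heart muscle genes and others enriched in the library with the heart profile. Myh6 was at 28.6 ± 3.56 CPM in the 4 other treated mice and 0.828 ± 0.358 CPM in vehicle mice (n = 5), and Pln at 15.2 ± 5.27 CPM against 2.17 ± 0.643 CPM. Outside those genes, Zfp7 was at 11.7 ± 1.02 CPM in treated and 17.3 ± 2.27 CPM in vehicle mice, and Ier3 at 14.7 ± 2.72 CPM against 23.6 ± 3.65 CPM. For both genes every treated mouse lay below every vehicle mouse. Zfp7 and Ier3 did not pass edgeR's test (adjusted p 0.0684 and 0.172), nor did Mylk3 (adjusted p 0.17), whereas Zfp7 and Ier3 passed DESeq2's (adjusted p 0.00514 and 0.0305).

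With all 19 libraries edgeR called 0 genes in this comparison, as did DESeq2 and limma-voom, and 1402 genes had an unadjusted p under 0.05 where chance gives 826. Among genes with a mean log2 CPM of at least 1, the 5 smallest p-values belonged to Myh6, Pln, Tnnc1, Ttn and Hspb7 (edgeR adjusted p 0.0841 to 0.119). With 18 libraries edgeR called 27 genes, all higher, and 608 genes had an unadjusted p under 0.05 where chance gives 821. All 27 were among the 241 genes that were enriched in the library with the heart profile. Pln rose by 2.81 on the log2 scale (edgeR adjusted p 6.89e-06) and Hspb7 by 1.2 (edgeR adjusted p 0.00639). Without the enriched genes edgeR called 0 genes. DESeq2 called 36 genes with 18 libraries and limma-voom 34. Of the 36, 33 were enriched genes and 3 were not (Zfp7, Ier3 and Sagsin1, whose fitted fold change was not bounded). None of the 23 tested genes chosen beforehand was called, and adjusted over the list alone there were 0. With 18 libraries their log2 fold changes ran from -1.54 to 0.52, with an edgeR adjusted p of 1 for each. In simulated data of the same depth and group sizes, edgeR called 86.6% of genes changed 2-fold and 38.8% of those changed 1.5-fold with 18 libraries. With 19 it called 53.7% and 2.99%. The changes were set only in genes above a floor of mean CPM, and genes varied independently, so power over all tested genes may be lower.

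Interferon-stimulated, MHC class II and tubular injury lists were lower, and the red blood cell and proximal tubule lists higher, in treated BPH/2J mice by camera with the preset correlation in the 18-library fit, but none of these was called with an estimated correlation or by fry. The urothelium list was also lower, with a median log2 fold change of -3.06 and 6 of 7 tested members lower when adjusted over the list alone, but it was not called by fry or with an estimated correlation (adjusted p 0.268). That test called 18 of 42 lists with 18 libraries and 20 with 19. The matrix list was lower with 18 libraries and higher with 19, and the proximal tubule list was higher with 18 and lower with 19. With an estimated correlation camera called only the neutrophil list, higher in treated mice in both fits (adjusted p 0.0187 with 18 libraries and 0.00754 with 19). With 18 libraries it had 5 tested members, of which S100a8 and S100a9 were higher and Lcn2 lower when adjusted over the list alone. Fry called 0 lists with 18 libraries and 1 with 19. Among the treated mice, BPH/2J Cmpd17b replicate 5 had the highest mitochondrial share of the 18 libraries, at 26.19%. Its 10 most abundant genes held 34.32% of its counts.

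**Figure D5:**
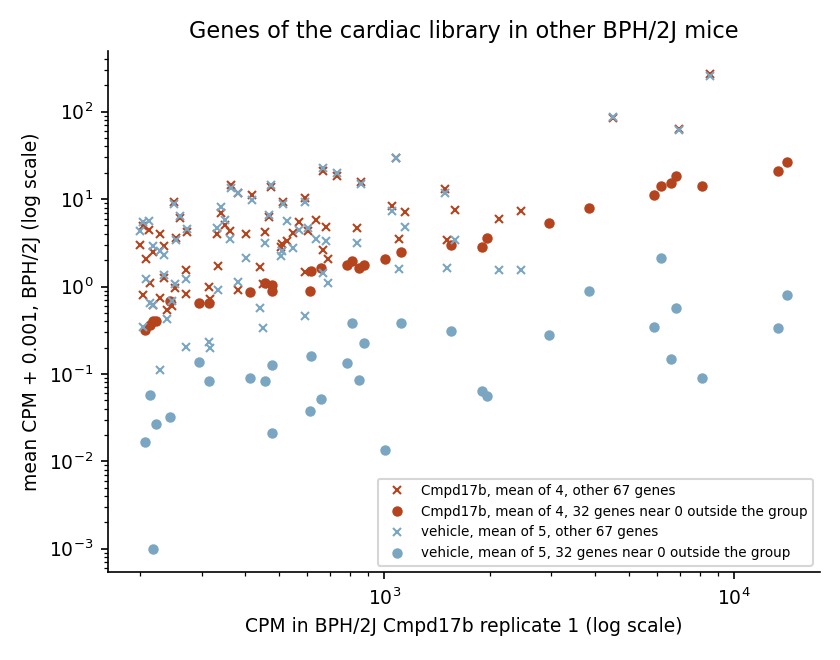
Mean CPM in the 4 other treated and the 5 vehicle BPH/2J mice (vertical, log axis, 0.001 added) against CPM in BPH/2J Cmpd17b replicate 1 (horizontal, log axis) for 99 genes at 200 CPM or more in that library; 1 point is 1 gene and group. Circles are 32 genes near 0 outside the treated BPH/2J group, which lie higher in treated than in vehicle mice.

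The effect of Cmpd17b in BPN/3J asks the same of the normotensive kidney. Among genes with a mean log2 CPM of at least 1, those with the smallest p-values with 18 libraries were Slc16a1, Dtx4 and Npas2, which were higher, and Srd5a2 and Tgm1, which were lower. Srd5a2 was at 21.8 ± 2.27 CPM in treated (n = 5) and 30.3 ± 2.75 CPM in vehicle mice (n = 4), and Slc16a1 at 31.2 ± 8.14 CPM against 15.3 ± 3.86 CPM. None of these 5 passed edgeR's test with 18 libraries (adjusted p 0.737 to 0.769). With 19 libraries the smallest p-values belonged to Npas2, Acvr2b, Dtx4, Per2 and Xbp1 (edgeR adjusted p 1 for each). edgeR called 0 genes in both fits. With 18 libraries 415 genes had an unadjusted p under 0.05 where chance gives 821, and with 19 it was 144 against 826. DESeq2 called 6 genes with 18 libraries (Dtx4, Fgf18, Npas2, Slc16a1, Sprr2a1 and Srd5a2) and 0 with 19, and limma-voom called 0 in both. In simulated data with the same limits edgeR called 79.1% of genes changed 2-fold and 31.3% of those changed 1.5-fold with 18 libraries. None of the genes chosen beforehand was called, and adjusted over the list alone there were 0.

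Endothelial and matrix lists were higher and the circadian clock list lower in treated BPN/3J mice by camera with the preset correlation, but with an estimated correlation it called 0 lists in either fit. The preset test called 21 lists with 18 libraries and 18 with 19. With an estimated correlation no list passed (adjusted p 0.199 for the endothelial list and 0.177 for the clock list with 18 libraries), and fry called 0 in both fits. Within the clock list 2 genes were higher and 6 lower when adjusted over the list alone, and Per2 was at 15.8 ± 4.75 CPM in treated and 29.8 ± 6.42 CPM in vehicle mice.

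The interaction tests whether the effect of Cmpd17b differs between the strains. Heart muscle genes again carried it: with 18 libraries edgeR called Pln, Tnnt2, Ckm, Myl3 and Myh6, all with a larger rise in BPH/2J, and all 5 were among the genes enriched in the library with the heart profile. Among genes with a mean log2 CPM of at least 1, those with the smallest p-values also held Ryr2, Zbed5, Trib2 and Hspb7, which did not pass (edgeR adjusted p 0.672 to 1). Leaving out 1 further library gave 1 to 6 calls. In that fit 529 genes had an unadjusted p under 0.05 where chance gives 821. With all 19 libraries edgeR called 0 genes, with 517 at an unadjusted p under 0.05 where chance gives 826. DESeq2 and limma-voom also called 0 there. With 18 libraries DESeq2 called 14 and limma-voom 7. Camera with the preset correlation called 26 lists with 18 libraries and 21 with 19, and with an estimated correlation 0 in both. MHC class II, interferon-stimulated and matrix lists were lower and red blood cell transcripts higher in that term with 18 libraries (estimated-correlation adjusted p 0.235 for each).

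Reversal of the strain difference by Cmpd17b was measured as the correlation, across genes, of the treatment effect in BPH/2J with the vehicle strain difference. Shared vehicle libraries push this correlation below 0. Unchanged groups simulated with 18 libraries, without a strain difference, gave a mean of -0.465 (central 95% of the draws from -0.856 to 0.169). The observed value was -0.0693. The observed covariance was -0.0173 against -0.0529 in the simulation. With the vehicle mice divided so that no library served both effects, the mean correlation over 20 divisions was 0.112 (range -0.0492 to 0.253) with 18 libraries and 0.113 with 19. Unchanged groups simulated in the same way gave -0.62 to 0.515 in the central 95% of the draws. These draws held no strain difference, unlike the data, so their bounds do not decide whether the observed values differ from no change. Single simulations with a strain difference gave a mean slope over the divisions of -0.00123 with a share of 0 reversed and -0.306 with a share of 0.5. The observed mean slope was 0.0669 (range -0.0366 to 0.165). A value below 0 would be needed for reversal. On an axis from BPN/3J at 0 to BPH/2J at 1, vehicle BPH/2J mice lay at 0.864 ± 0.142 (n = 5) and treated mice at 0.933 ± 0.143 (n = 4), with a two-sided exact permutation p of 0.476 over 126 assignments. With all 19 libraries the positions were 0.862 and 0.959 (exact permutation p 0.31). Reversal was not detected.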

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

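The tests of the heart profile, of a shared proportion of heart transcripts, of transcript length and of the surrogate variable, and all fits on 18 libraries, were chosen after the results had been seen.

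The library labelled BPH/2J Cmpd17b replicate 1 stood apart from the 4 others of its group in its median correlation with all libraries, with a gap of 0.8727 of the group's range. Kidney mixed with heart tissue is argued against by proximal tubule genes at 0.227% of their usual level, and a response of the kidney to Cmpd17b by heart genes in the other 4 treated BPH/2J mice at a median of 0.231% of this library. Of the 30 heart genes, 27 reached 20 CPM in this library and 11 had a mean above 1 CPM in vehicle BPH/2J mice. Heart RNA under a kidney label stays open, and the same proximal tubule value of 0.227% is what it needs; the study also examined the left ventricle, whose data were not used here.

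Heart genes were higher in the other 4 treated BPH/2J mice than in vehicle mice, and the interaction in log2 was 2.95 for Pln, 5.18 for Tnnt2, 5.35 for Ckm, 5.2 for Myl3 and 4.08 for Myh6. Among the 99 enriched genes at 200 CPM or more in the library with the heart profile, 22 had no excess in these mice; over the other 77 the slope of log2 excess on log2 level was 0.888 (95% interval 0.723 to 1.05, r squared 0.607), and a slope of 1 is what carry-over of a fixed share predicts. Over all 99, the third quartile of the share was 3.11 times the first, with a bootstrap interval that started at 1.66 and had no finite upper bound, so this set leaves open whether kidney cells switched on some of these genes. A narrower set of 32 genes, chosen after the wider result had been seen because kidney expression hid small shares in many of the 99, gave a slope of 1.01 (0.963 to 1.06) and a quartile ratio of 1.18 (1.08 to 1.34). The 4 libraries held these 32 genes at a median of 0.192% to 0.197% of that library and the others at no more than 0.017%, a level that the choice of the genes keeps low by construction; for the 99 genes it was 0.351% to 0.49% against up to 0.344%. Carry-over may account for edgeR's 27 calls in BPH/2J, which were all among the enriched genes (the 0 calls left without them restate this), but not for the 3 lower of the 31 calls of edgeR with 1 surrogate variable (Noxred1, Rsc1a1 and Sap18b) or the 3 genes outside that set that DESeq2 called; where it would have happened was not tested.

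Within groups, the 18 libraries were spread along 1 axis that held 35.7% of the within-group variance. Its loadings followed transcript length, with a Spearman rho of -0.39 across the 90.8% of genes with a length, which may reflect RNA integrity or fragment selection. Thick ascending limb genes lay lower on it than length-matched random lists (percentile 0.1), so a difference in the tissue sampled is also open. The random genes were drawn independently, unlike markers of 1 cell type, and only this list was tried. The percentile therefore does not single out that segment. Whether the axis adds to the strain calls stays open. A share of 0.995 of the vehicle strain calls remained with 1 surrogate variable. That variable was only weakly related to strain in vehicle mice (Pearson r -0.277, n = 9), so it could hardly remove strain calls, which decides nothing. The axis itself is centred within groups.

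Of 188 groups examined for a library far from the rest of its group, 17 stood out where chance gives 9.4. Besides the correlation above, they were total counts in BPH/2J vehicle replicate 5 (low), genes detected in BPH/2J Cmpd17b replicate 4 (high), Ren1, Acta2 and Icam1 in BPH/2J Cmpd17b replicate 5 (high), Col1a1 and Vcam1 in BPH/2J vehicle replicate 2 (high), Tmem267 in BPH/2J vehicle replicate 5 (high) and in BPN/3J vehicle replicate 2 (low), Angptl7 in BPN/3J vehicle replicate 2 (low), Ccn2 in BPN/3J vehicle replicate 4 (high), Serpina1a in BPN/3J vehicle replicate 1 (low), Agtr1a in BPN/3J Cmpd17b replicate 3 (high), Havcr1 in BPN/3J Cmpd17b replicate 2 (low), Ugt1a10 in BPN/3J Cmpd17b replicate 5 (low) and Thrsp in BPN/3J Cmpd17b replicate 1 (high). The gap as a share of the group's range was, in that order, 0.7246, 0.756, 0.9139, 0.8642, 0.8444, 0.7142, 0.8229, 0.9039, 0.8291, 0.9111, 0.9507, 0.8658, 0.7141, 0.7716, 0.8688 and 0.9286.

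Other splits of the same mice tested whether an arbitrary grouping of the mice gives as many calls. For the vehicle strain difference the real split was the 1 of 100 with the most genes: 566 against at most 18 elsewhere with 19 libraries, and 1766 against at most 1260 with 18. For the treated strain difference it was again 1 of 100, with 1446 against at most 118 and 1701 against at most 748. An arbitrary grouping of the mice is thus unlikely to give the number of strain calls, although 1 of 100 is the lowest share such a draw can reach. The split with 1260 genes was itself close to the strain split. It set the 4 vehicle BPN/3J mice and BPH/2J vehicle replicate 1 against the 4 other vehicle BPH/2J mice. For Cmpd17b in BPH/2J with 18 libraries, 5 of 100 splits gave at least 27 genes, the highest other being 4855, so the splits did not exclude chance for the number of calls; a smaller draw made earlier gave a share below the threshold, so the result sits at the border. The split with 4855 genes grouped vehicle replicates 3 and 5 with Cmpd17b replicates 3 and 5, which points to a structure of the samples that such splits follow. These libraries had the highest mitochondrial shares of the BPH/2J libraries in that fit, at 19% to 26.19%. They also had the highest scores on the axis within groups described above. Whether that axis accounts for the calls of this split was not tested. The splits do not test single genes: Myh6 was at 26.6 to 33.9 CPM in the 4 treated mice and at 0.381 to 1.25 CPM in the 5 vehicle mice (edgeR adjusted p 7.27e-06). Where the real count was 0, all 100 of 100 splits reach it by construction, so the splits say nothing about chance for Cmpd17b in BPH/2J with 19 libraries (highest other 2224), for Cmpd17b in BPN/3J in both fits (highest other 1) and for the interaction with 19 libraries (highest other 0). For the interaction 2 of 100 splits, the real one among them, gave at least 5 genes with 18 libraries (highest other 5047). That share is below the threshold but was not adjusted for the number of split tests. The split with 5047 genes grouped the same BPH/2J libraries and again points to a structure of the samples. All 5 called genes were enriched in the library with the heart profile, so the count says nothing on other genes.

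Counts of gene lists called with the preset correlation mostly did not stand apart from other splits. With 19 libraries, as many lists were called in 54, 74, 32, 7 and 20 of 100 splits for the vehicle strain, treated strain, BPH/2J treatment, BPN/3J treatment and interaction comparisons, against real counts of 11, 13, 20, 18 and 21 and highest others of 23, 26, 27, 19 and 28. With 18 libraries the numbers were 49, 77, 24, 8 and 2 of 100, against real counts of 15, 6, 18, 21 and 26 and highest others of 25, 15, 23, 24 and 26. Only the 18-library interaction had a share below the threshold, not adjusted for the number of split tests. There another split also reached 26 lists, and the structure of the samples noted for the gene counts may also act. Camera with an estimated correlation and fry each called 0 lists there.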

How the results depend on the processing

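The alternatives run on 18 libraries were chosen after the data were seen; those on 19 were planned. No paired analysis was possible because the labels give each mouse its own number and no number is shared between groups.

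With 19 libraries, edgeR's 566 vehicle strain calls became 967 with DESeq2, 1367 with 1 surrogate variable and 1476 with only the groups compared. The 1446 treated strain calls became 838 with limma-voom (355 higher and 483 lower, against 980 and 466), 3181 with 1 surrogate variable and 322 with only the groups compared. The 0 calls for Cmpd17b in BPH/2J became 31 with 1 surrogate variable. Lists called in all comparisons fell from 83 to 1 with an estimated correlation and 9 with fry. The 1 call among the genes chosen beforehand became 6 with DESeq2 and 11 with 1 surrogate variable. The fit of only the vehicle groups does not hold the library with the heart profile. The fit of only the treated groups gave 1330 calls without that library. Other causes of these changes were not tested.

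With 18 libraries, the 1766 vehicle strain calls became 2684 with 1 surrogate variable and 880 with an absolute log2 fold change of at least 1, and that threshold left 980 of the 1701 treated strain calls. DESeq2 called 6 genes for Cmpd17b in BPN/3J, against 0, and 14 for the interaction, against 5. Leaving out the genes enriched in the library with the heart profile took Cmpd17b in BPH/2J from 27 to 0 and the interaction from 5 to 0, since all called genes were among those left out. The same step took the treated strain calls from 1701 to 1607 and the vehicle strain calls from 1766 to 1750. Lists fell from 86 to 1 with an estimated correlation and 22 with fry. The mean reversal correlation rose from 0.112 to 0.239 with strain genes called from the remaining vehicle mice; the cause was not tested.

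Leaving out each library in turn, with 19 libraries, gave 349 to 1766 vehicle strain calls, 789 to 1812 treated strain calls, 0 to 37 for Cmpd17b in BPH/2J, 0 to 5 for the interaction and 0 to 8 of the genes chosen beforehand. The 1766, 5 and 8 came without BPH/2J Cmpd17b replicate 1, and the other refits gave at most 704, 0 and 4. Vehicle strain calls fell to 361, 363 and 349 without BPN/3J vehicle replicates 1, 2 and 3, and treated strain calls to 960, 795, 789 and 870 without BPN/3J Cmpd17b replicates 1, 2, 3 and 4. For Cmpd17b in BPH/2J there were 27, 36, 37, 37 and 28 calls without Cmpd17b replicates 1, 2, 3, 4 and 5. Lists ranged from 79 to 86 and the reversal correlation from 0.0578 to 0.15. With 18 libraries the ranges were 1226 to 2490, 1290 to 1749, 21 to 30 and 0 to 0 for the strain and Cmpd17b comparisons, 1 to 6 for the interaction (over 1.5 times from 5 in 14 of 18 refits, that is in all but those without BPN/3J vehicle replicate 3, BPN/3J Cmpd17b replicates 1 and 3 and BPH/2J vehicle replicate 4), 73 to 90 lists, 2 to 13 of the genes chosen beforehand and 0.00349 to 0.166 for the reversal correlation, which was lowest without BPH/2J Cmpd17b replicate 5. Cmpd17b in BPN/3J stayed at 0 in every leave-one-out fit. Pdk4 and Hk2 reversed in the treated strain comparison of the 19 libraries without BPH/2J Cmpd17b replicate 1, to a log2 fold change of -0.0615 and -0.903, and over all refits they ranged up to 4.26 and 6.76 (both without BPN/3J Cmpd17b replicate 1); the library left out carries both genes with its heart profile. DESeq2 size factors moved the median log2 fold change by at most 0.0185.

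Small effects were often missed at these depths and group sizes, which were not varied: edgeR called 29.9% of simulated 1.5-fold changes in the vehicle strain comparison with 18 libraries. With 19 libraries it called 4.48%, and the biological coefficient of variation was 0.418 against 0.251.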

Other observations

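The clock test and the relations across libraries were chosen after the results had been seen, as was the use of 18 libraries for the neighbour test; each explanation is a hypothesis from the same data.

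Strain genes may sit in chromosome blocks that differ between the strains. Among the 1045 placed genes called in the same direction in both arms with 18 libraries, 154 pairs of neighbouring genes were both called, 2.37 times the mean of 65 over 10000 shuffles (p 1e-04, the smallest the shuffles can give). Of these pairs, 99 went in the same direction. The same number of top genes of the BPN/3J treatment comparison gave 85 pairs. This is also above the mean of the shuffles but below their highest of 100, and it was not tested. The longest run held 7 genes and ended at Tmem267.

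A shift in clock phase or in the time of collection may lie behind Npas2 and Per2 in treated BPN/3J mice. A score of 5 clock genes minus 11 others averaged 0.99 ± 1.39 (n = 5) in treated and -1.01 ± 0.668 (n = 4) in vehicle BPN/3J mice, with a two-sided exact permutation p of 0.0397. In BPH/2J mice the exact permutation p was 0.254, with a difference of 0.791 against 2. The p-values are not adjusted for the 2 strains, the genes were picked from the pattern they test, and the difference between the strains was not tested. The times of collection are not given in the sources used here.

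Across the 18 libraries, the axis within groups correlated with the animal number (Pearson r 0.609, permutation p 0.0072, adjusted 0.011; Spearman rho 0.589, permutation p 0.011, adjusted 0.017), and r was 0.628 without the 2 libraries farthest from the median. Its relation to the mitochondrial share of counts had a Pearson r of 0.586 (permutation p 0.011, adjusted 0.011). The Spearman rho was 0.195 (permutation p 0.44, adjusted 0.44), and r was 0.0923 without the 2 farthest libraries. The share was not centred within groups and differed by strain. Its group means were 14.1% and 13.6% in BPN/3J and 18.5% and 19.7% in BPH/2J. The r without 2 libraries thus does not decide whether the axis follows the share within groups. In every group but vehicle BPH/2J the library highest on the axis had the highest share. Neither relation was tested with both sides centred. These belong to a family of 3 relations, the other being with the surrogate variable (Pearson r -0.849, permutation p 7e-05, adjusted 0.00021; Spearman rho -0.699, permutation p 0.0017, adjusted 0.005; r -0.661 without the 2 farthest).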
